A study of Mus musculus with 6 samples.

How the data were processed

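RNA sequencing libraries were made from mouse L929 fibroblasts with a standard Illumina preparation, per the labels, which give total RNA as the molecule and do not say how mRNA was selected. The 6 samples fall into 3 control libraries and 3 libraries from cells given TNF-α (10 ng/ml) with actinomycin D (1 µg/ml) for 12 hours. The labels carry the same treatment text on control samples, and the group was taken from the sample titles and treatment labels. Nothing in the labels says that libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Columns were matched to samples by treatment name and number, where control columns carry the genotype name.

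The deposited count table holds whole-number counts for 54532 Ensembl genes with symbols, coordinates, biotypes and gene lengths. HISAT2 2.1.0, RSEM 1.3.1 and DESeq2 1.24.0 and the builds GRCm38 and mm10 are named per the submitters' processing notes, without role or order. Whether counting used strand, and how reads shared between copies were assigned, is not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain. The deposited FPKM table holds, for each library, the count divided by the deposited gene length (a value of type other, in bases, per the file headers) times 1 constant. That constant was 0.635 to 0.719 of the value by library total in controls and 1.22 to 1.64 in treated libraries, so the authors' FPKM values carry a size factor beyond the library total. Of the gene identifiers, 54495 are in the GENCODE annotation of GRCm38 used here and 53499 have the same coordinates; coordinates are those of the deposited table.

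Genes were kept by edgeR's filterByExpr, which left 13290 of 24708 genes with a count. Counts were scaled by TMM factors and tested with edgeR 4.0.16 (glmQLFit with robust estimation, glmQLFTest) in R 4.3.3, treated against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM-scaled; log2 CPM uses a prior count of 2. A standard error is the log2 fold change divided by the root of the F statistic. Before the data were examined, 29 gene lists were fixed, of which 25 had at least 5 tested members; these were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The 4 lists too small for the test hold macrophage, lymphocyte, epithelial and endothelial markers. Lists can share genes. The values of 1 list member are not reported here. Gene biotypes were tested with camera at the preset and at an estimated correlation. Shares of counts were compared with an exact two-sided permutation test, which cannot go below 0.1 with 3 against 3; 15 classes were tested, and after Benjamini-Hochberg adjustment the lowest value was 0.125.

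Named genes follow a rule fixed in advance: the 8 largest rises and 8 largest falls among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between groups; for each list up to 2 of the largest rises and 2 of the largest falls with a mean of at least 1 CPM; and Tnf, Tnfrsf1a, Tnfrsf1b, Nfkbia, Tnfaip3, Ripk1, Casp8, Mdm2 and Cdkn1a in every case. Members of the small marker lists are named after their values were seen. A group at 0 is set against a floor of 3 counts over the group; intervals are exact and, with the floor, cover counting error only.

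Alternatives were other scaling factors, no filter or a stricter one, DESeq2 1.42.0, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with a mean FPKM of at least 1, a replicate block, a gene length offset from a lowess trend with span 0.3, protein-coding genes only, and leaving out each library. A GC content offset was added after the data were seen. The fits were tested on simulated data with 200 changed genes. These used the real library sizes and dispersions and, for each gene, 1 mean pooled over the 6 libraries. For treated against control, over 12929 genes, edgeR recovered 53 of 100 genes changed by 1 on the log2 scale and 94 of 99 changed by 2. There were 5 false calls among 152. With a length bias added, 265 of 425 calls over 13002 genes were false, and 6 of 148 after the length offset. That bias was linear, 0.3 on the log2 scale per SD of log2 length. It was weaker than the trend in the data, where medians by length bin ran from 1.78 to −1.27. The offset was thus not checked at the size of the real trend. A list shifted by 1 was called and 0 of 24 unchanged lists were. Simulated genes were drawn independently, so the preset correlation of the list test could not be checked this way. The simulated changes were few and balanced in direction, so scaling under a large shift in composition was not checked either. Gene features for the closing tests came from the same GENCODE annotation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.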

Results

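RNA sequencing compared untreated L929 cells, a mouse fibroblast line widely used to study cell death induced by tumour necrosis factor, with L929 cells given TNF-α at 10 ng/ml and actinomycin D at 1 µg/ml for 12 hours. TNF-α is an inflammatory cytokine, and actinomycin D binds DNA and blocks transcription by RNA polymerases. Each group held 3 libraries. Library totals ran from 16056207 to 18036322 counts, so depth was close to even. The question was how gene expression differed between treated and untreated cells. No group received either agent alone, so every difference belongs to the combination. Within groups, log2 CPM values correlated across genes at 0.957 to 0.991, and the first principal component, with 86.8% of the variance, separated treated from control libraries. On that component treated replicates 1, 2 and 3 lay at 124, 109 and 77.7, so replicate 3 was nearest the controls (−109 to −97.0). In the same order these libraries had 15705, 17688 and 18849 genes with a count, against 19219 to 20116 in controls. Treated replicate 1 stood apart from treated replicates 2 and 3 on the next component, which held 6.93%.

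The largest rises in treated cells included the chemokine genes Cxcl1, Cxcl2 and Ccl20 and the transcription factor genes Fos, Fosb and Egr2, and the largest falls included Chst13, Plk1 and Cdca2. Cxcl1 rose from 19.96 ± 1.71 to 1282 ± 217 CPM (SD, n = 3 libraries per group), a log2 fold change of 6.005 ± 0.216 (SE). Cxcl1 lies on chromosome 5 from 90891241 to 90893115. Its neighbour Cxcl2 held 3 counts over the control libraries and 1727 over the treated ones, a ratio of 1191 with a 95% counting interval of 407 to 5780. Ccl20, a chemokine for CCR6-bearing lymphocytes, reached 45.0 ± 8.7 CPM from 0.15 ± 0.14. The early-response transcription factors Fos, Fosb and Egr2 rose by log2 fold changes of 6.13 ± 0.34, 5.74 ± 0.31 and 5.91 ± 0.38. Tnfrsf1a, which encodes TNF receptor 1 and spans chromosome 6 from 125349362 to 125362484, fell from 67.6 ± 10.2 to 1.68 ± 0.40 CPM, a log2 change of −5.33 ± 0.25, just short of the 8 largest falls. The mitotic kinase gene Plk1 fell from 85.4 ± 14.7 to 1.61 ± 0.55 CPM, and Cdca2, a chromosome-associated regulator of protein phosphatase 1, changed by −5.84 ± 0.52. Chst13, a chondroitin sulfotransferase gene, had 1030 counts over the controls and 0 over the treated libraries, at least 166-fold lower against a floor of 3 counts over the group. The corepressor gene Bcor (−5.89 ± 0.32), the phosphatase subunit gene Ppp2r2a (−5.69 ± 0.34), Rnf219 (−5.54 ± 0.36), Nufip1 (−5.82 ± 0.52) and the calcium channel gene Orai1 (−5.42 ± 0.60) completed the 8 largest falls. Adjusted p-values from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran up to 1.48e-05 among these named genes. The remaining pair among the largest rises, Gm14632 and Gm11808, had far higher values in 1 treated library than in the others. Gm14632 had 44.1 CPM in treated replicate 2 against 1.501 and 0.687 in the others, and without that library its log2 change of 5.73 became 1.86 (adjusted p = 0.16). Gm11808 had 2130 CPM in treated replicate 1 against 173 and 134, and its change of 5.69 became 3.21 without that library, where the call was kept (adjusted p = 1.1e-05). Neither call was kept without control replicate 2 or 3, and that of Gm14632 was also lost without control replicate 1. Both were lost with no filter, with a replicate block and with mitochondrially encoded genes held equal. Their counts may be shared with near-identical genes and are uncertain. Leaving out 1 library moved the change of Ccl20 from 8.18 to 8.97 (control replicate 2), of Cxcl2 from 10.00 to 10.73 (control replicate 3) and of Cdca2 to −6.52 (treated replicate 3). Nufip1 went to −6.57 without treated replicate 1 and −5.23 without treated replicate 3, and Orai1 went to −7.79 without treated replicate 2.

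**Figure D1:**
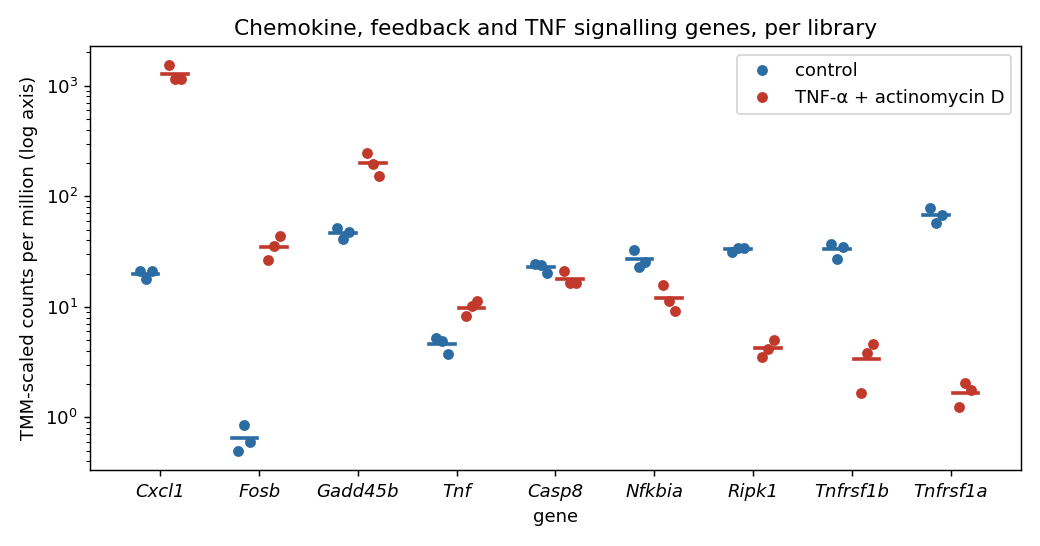
TMM-scaled CPM (counts scaled to library size) on a log axis for 9 genes. Each dot is 1 library, blue for control and red for TNF-α with actinomycin D (n = 3 per group), and each bar is a group mean; Cxcl1 rises from a mean of 19.96 to 1282 CPM, Tnfrsf1a falls from 67.6 to 1.68 CPM, and the Casp8 dots of both groups lie close together. With ribosomal protein or mitochondrially encoded genes held equal, Tnf is called lower (log2 change −1.28 and −1.06, respectively). Gadd45b is then at −0.34 and −0.044 and is not called.

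Across the transcriptome, 4604 of 13290 tested genes were higher and 5337 lower at an adjusted p of 0.05, and 3601 and 4395 of them changed at least 2-fold. The other 3349 did not pass. Control and treated values did not overlap for 10348 genes, where chance gives 10% of the genes. Direction depended on the scaling. TMM factors averaged 1.44 ± 0.093 in controls and 0.699 ± 0.086 in treated libraries, so scaling by library size alone lowered the median log2 change of tested genes by 1.04. It fell by 2.39 when ribosomal protein genes were held equal and by 2.13 when mitochondrially encoded genes were, and rose by 0.11 with median-ratio factors and 0.16 with upper-quartile factors. Called genes split into 46.3% higher with TMM, 22.3% (2276 higher, 7924 lower) by library size, 2.18% (244 and 10955) with ribosomal protein genes held equal and 3.25% (345 and 10281) with mitochondrially encoded genes held equal. The mitochondrial scale rests largely on rRNA, which went from 0.041% of counts in controls to 1.54% in treated libraries. Mitochondrial mRNA went from 1.03% to 0.686%, and holding it equal alone was not tried. Total RNA per cell was not measured, so each change is relative to the TMM scale and is not an amount per cell. A change in share of counts corresponds to the fit by library size alone, where the median is lower by 1.04. List medians below are given relative to the median of all tested genes, a difference that these scalings barely move.

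Inflammatory targets of TNF moved upward as a group, while components that sense and relay TNF moved downward. Of 28 tested inflammatory targets, 21 rose and 3 fell, with a median 2.25 above that of all genes on the log2 scale (camera adjusted p = 8.1e-06; adjusted p = 0.198 with an estimated correlation). The other 16 of 44 listed targets had too few counts to be tested. Members near 0 in controls, such as Cxcl2, pass the expression filter through their treated counts. The list median of 2.08 is smaller than the 2.39 by which holding ribosomal protein genes equal lowers all genes. Beside the chemokines, Csf1, the macrophage growth factor gene, fell from 1436 ± 164 to 512 ± 45 CPM. Of 31 TNF receptor and death-signalling components, 21 fell and 4 rose, with a median 1.09 below that of all genes (camera adjusted p = 0.0094; adjusted p = 0.439 with an estimated correlation), a call lost once the gene length trend was removed (0.76 below, adjusted p = 0.097). Tnfrsf1b, the second TNF receptor, changed by −3.29 ± 0.32 and Ripk1, the kinase recruited to the receptor complex, by −2.96 ± 0.21. Ripk3, the necroptosis kinase gene, rose from 115 ± 13 to 335 ± 25 CPM, and Rbck1, part of the linear ubiquitin ligase, rose by 1.295 ± 0.150; both turn negative with ribosomal protein or mitochondrially encoded genes held equal, and the Rbck1 call is lost by library size alone. Casp8, the initiator caspase gene, was at 22.8 ± 2.2 and 17.8 ± 2.7 CPM (adjusted p = 0.117), and was called lower without treated replicate 1 (log2 change −0.57), by library size alone (−1.40), with ribosomal protein (−2.77) or mitochondrially encoded genes (−2.48) held equal, and once the gene length trend was removed (−0.47, with or without a replicate block). Tnf itself had 4.64 ± 0.78 CPM in controls and 9.84 ± 1.52 after treatment (adjusted p = 0.0023), a call lost by library size alone or once the gene length trend was removed, and negative with either gene class held equal. Among 24 NF-κB feedback regulators, 4 rose and 13 fell, and the list as a whole did not pass (camera adjusted p = 0.252), though it did by fry (adjusted p = 0.012, down). Nfkbia, the NF-κB inhibitor gene, changed by −1.15 ± 0.24, Nfkb1 by −2.29 ± 0.19 and Tnfaip8 by −2.84 ± 0.28. Ier3 rose by 2.88 ± 0.16, a call lost with ribosomal protein genes held equal. The stress gene Gadd45b rose by 2.096 ± 0.195, and was negative but not called with either class held equal. Tnfaip3, the deubiquitinase gene for A20, had 7.77 ± 0.65 and 7.36 ± 1.04 CPM (adjusted p = 0.777), and was called higher by 0.83 once the gene length trend was removed (0.84 with a replicate block), but lower by library size alone (−1.10) and with ribosomal protein (−2.44) or mitochondrially encoded genes (−2.24) held equal. BCL-2 family, caspase and apoptosome genes went both ways, with 12 of 33 higher and 14 lower (camera adjusted p = 0.922); Bid, a proapoptotic BH3 gene, fell by 4.26 on the log2 scale, while Cycs, for cytochrome c, and Casp1 rose by 2.36 ± 0.20 and 2.17 ± 0.19. Those rises turn negative with ribosomal protein genes held equal and are not called with mitochondrially encoded genes held equal. The median and mean of that list lay below all genes while its test pointed upward.

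mRNAs for ribosomal proteins, nuclear-encoded oxidative phosphorylation subunits, lysosomes and extracellular matrix lay above the median of all genes after treatment. Of 82 cytosolic ribosomal protein genes, 81 rose, with a median 2.59 above that of all genes (camera adjusted p = 8.0e-19; adjusted p = 0.439 with an estimated correlation); with these genes held equal, their own median is −0.03 by construction. Rplp1, a ribosomal stalk protein gene, went from 1162 ± 220 to 10361 ± 3272 CPM, and reads shared with its processed copies make single members uncertain. Among 75 nuclear genes of oxidative phosphorylation, 74 rose (median 2.61 above all genes, camera adjusted p = 4.7e-18; adjusted p = 0.439 with an estimated correlation; list median −0.01 with ribosomal protein genes held equal). Atp5e, an ATP synthase subunit gene, reached 1363 ± 487 CPM from 137 ± 24. Of 38 lysosomal genes, 36 rose and 1 fell (median 2.39 above all genes, camera adjusted p = 3.6e-11; adjusted p = 0.424 with an estimated correlation), and their median turns to −0.19 with ribosomal protein genes held equal. Ctsd, for cathepsin D, rose from 107 ± 17 to 827 ± 169 CPM. Collagen, matrix and fibroblast genes had 27 of 30 members higher and 3 lower (median 1.63 above all genes, camera adjusted p = 2.0e-06; adjusted p = 0.439 with an estimated correlation), with a median below 0 when ribosomal protein (−0.96) or mitochondrially encoded genes (−0.68) are held equal and the call lost in the former case (1.61 above all genes, adjusted p = 0.067). Another 11 of the 41 listed matrix and fibroblast genes, Lum and Dcn among them, had too few counts to be tested. Sparc, a matrix glycoprotein gene, rose by 2.53 ± 0.18, a call lost with either class held equal. Pdgfra, for a platelet-derived growth factor receptor, changed by −1.61 ± 0.23, a call lost once the length trend was removed. Of 31 proteasome genes 24 rose and 2 fell (median 1.41 above all genes, camera adjusted p = 6.4e-05; adjusted p = 0.617 with an estimated correlation; list median −1.19 and −0.90 with the respective gene classes held equal), and the call is lost with ribosomal protein genes held equal (adjusted p = 0.73). Psmb3 rose by 2.25 ± 0.23 and Psma7 by 2.16 ± 0.23, and both turn negative with ribosomal protein genes held equal and are not called with mitochondrially encoded genes held equal.

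Mitochondrially encoded RNA was uneven. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose from 143 ± 25 to 15583 ± 451 CPM and from 141 ± 74 to 6308 ± 958 CPM. Mitochondrial rRNA thereby took 1.54% ± 0.28 of counts after treatment against 0.041% ± 0.017, and mitochondrial mRNA took 0.686% ± 0.196 against 1.03% ± 0.28. The exact two-sided permutation p was 0.1 for the rRNA, the smallest that 3 against 3 allow, and 0.2 for the mRNA. As a list, 7 of 14 mitochondrial mRNA and rRNA genes rose and 0 fell (camera adjusted p = 0.034; adjusted p = 0.629 with an estimated correlation). The list median lay 0.74 above all genes. The call was lost by library size alone, where the list median was −0.48 but still 0.74 above all genes. It was also lost without control replicate 1, treated replicate 1 or treated replicate 3 (camera adjusted p = 0.078, 0.066 and 0.084). The shifts there were 0.57, 0.76 and 0.67. Once the gene length trend was removed the median lay 0.47 below all genes (camera adjusted p = 0.458). The list median is negative with either gene class held equal. That list leaves out tRNA genes, of which 5 of 9 tested rose, mt-Tn by 4.83 ± 0.51 and mt-Tc by 4.91 ± 0.46 among them. Treated libraries were uneven for both, at 249 ± 190 and 232 ± 140 CPM. On the plus strand mt-Th (−4.07 ± 0.68), mt-Ts2 (−5.22 ± 0.73) and mt-Tl2 (−5.78 ± 0.72) fell and mt-Tw rose. The tested minus-strand tRNA genes (mt-Tn, mt-Tc, mt-Ty and mt-Tp) all rose, as did the minus-strand mRNA mt-Nd6 (1.29 ± 0.17). A difference between strands was not tested. Cytosolic ribosomal protein genes rose from 7.996% ± 0.63 to 20.7% ± 2.4 of counts and protein-coding genes fell from 97.0% ± 0.014 to 93.5% ± 0.22, each with an exact permutation p of 0.1.

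**Figure D2:**
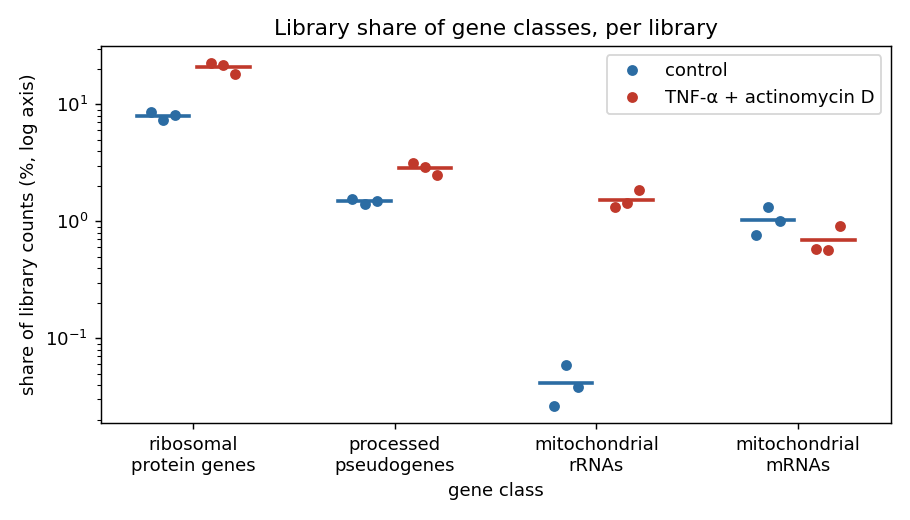
Share of library counts on a log axis for 4 gene classes. Each dot is 1 library, blue for control and red for TNF-α with actinomycin D (n = 3 per group), and each bar is a group mean; mitochondrial rRNA goes from 0.041% to 1.54% and ribosomal protein genes from 7.996% to 20.7%.

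Cell cycle genes, zinc finger genes and ribosome assembly factors were lower, and replication-dependent histone genes higher. Of 56 G2/M and mitosis genes 42 fell and 8 rose (median 1.38 below all genes, camera adjusted p = 6.4e-05; adjusted p = 0.156 with an estimated correlation). Plk1 and Cdca2 led the falls, while Cenpa, for the centromeric histone, and Ccnb2, for cyclin B2, rose by 1.81 ± 0.19 and 1.58 ± 0.16 and turn negative with ribosomal protein or mitochondrially encoded genes held equal. Without treated replicate 3 the change of Cdca2 was −6.52. Of 57 G1/S and DNA replication genes 38 fell and 6 rose (median 1.44 below all genes, camera adjusted p = 0.00019; adjusted p = 0.198 with an estimated correlation). E2f8, a repressor of the E2F family, fell from 71.3 ± 4.8 to 2.72 ± 0.89 CPM and Cdc6, a replication licensing gene, from 60.6 ± 5.7 to 2.76 ± 1.32 CPM. Numbered zinc finger genes, most of them DNA-binding repressors, had 176 of 275 members lower and 13 higher (median 1.29 below all genes, camera adjusted p = 1.6e-06; adjusted p = 0.439 with an estimated correlation). Zfp748 went from 305 to 3 counts, a treated to control ratio of 0.0203 (95% counting interval 0.0042 to 0.060). The last treated counts lie in treated replicate 3, and without it the fitted change moves from −5.51 to −9.34. Zfp36, whose product promotes decay of AU-rich mRNAs, belongs to the list by name and rose from 8.40 ± 1.89 to 90.8 ± 14.6 CPM. Of 49 nucleolar ribosome biogenesis genes 33 fell and 9 rose (median 0.99 below all genes, camera adjusted p = 0.0015; adjusted p = 0.339 with an estimated correlation). The helicase gene Ddx10 changed by −4.90 ± 0.46, or −5.68 without treated replicate 3, and Taf1c, of the RNA polymerase I initiation complex, by −4.08 ± 0.52, or −5.41 without that library. Nhp2, a box H/ACA particle protein gene, rose by 1.62 ± 0.23 and turns negative with either gene class held equal. All 14 tested histone genes rose (median 3.24 above all genes, camera adjusted p = 1.3e-05; adjusted p = 0.156 with an estimated correlation), at low levels. The other 53 of 67 listed histone genes had too few counts to be tested, and where control counts are as low as those of Hist1h4h (1, 5 and 5) a gene passes the expression filter through its treated counts. With no filter the median of 57 histone genes lay 2.70 above all genes. Hist1h4h had 3.54 ± 2.56 CPM after treatment and 0.15 ± 0.09 before, and its change of 4.50 became 3.74 without treated replicate 1.

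**Figure D3:**
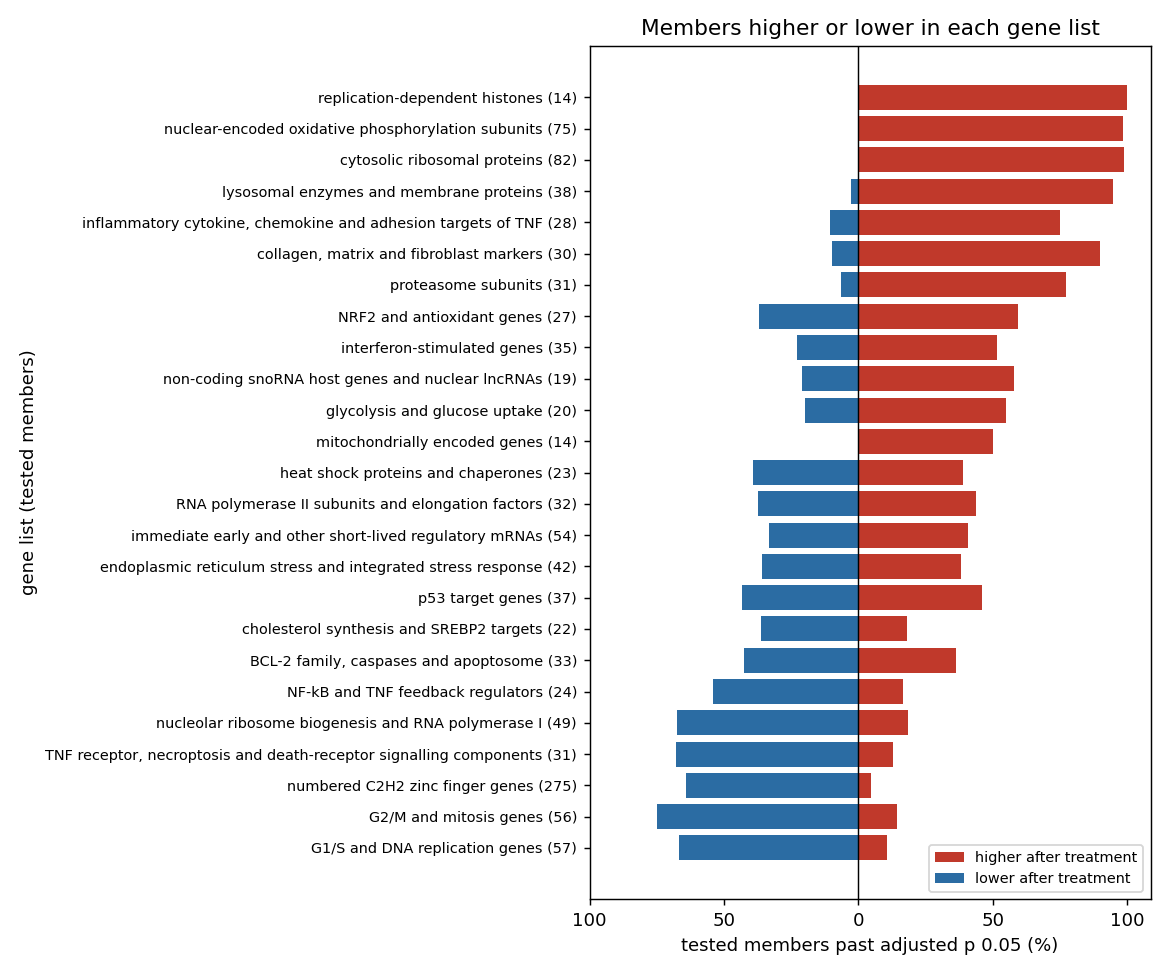
Percent of tested members past an adjusted p of 0.05 in each of 25 gene lists, with bars to the right (red) for members higher after treatment and to the left (blue) for members lower. Lists are ordered by median log2 fold change and numbers in brackets are tested members; 81 of 82 ribosomal protein genes are higher and 42 of 56 G2/M genes lower. Directions are for TMM scaling, and medians of lists with mostly higher members fall to near or below 0 with ribosomal protein genes held equal, apart from histones (0.65).

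Stress and metabolic genes moved in both directions. Interferon-stimulated genes had 18 of 35 members higher and 8 lower (median 1.15 above all genes, camera adjusted p = 0.038; adjusted p = 0.279 with an estimated correlation), a call lost with upper-quartile factors (adjusted p = 0.052) and once the GC content trend was removed (0.058), though the shift stayed at 1.15 and 1.16, with a median below 0 by library size alone (−0.04) and with either gene class held equal. The other 20 of 55 listed interferon-stimulated genes, Ifit1, Mx1 and Rsad2 among them, had too few counts to be tested. Bst2, for tetherin, rose from 32.9 ± 3.9 to 288 ± 90 CPM, while the GTPase gene Irgm1 changed by −2.56 ± 0.28. The remaining lists did not pass as a whole, with camera adjusted p-values of 0.052 for snoRNA host genes, 0.082 for glycolysis and for NRF2 targets, and 0.252 to 0.801 for the others. The snoRNA host list does pass in 8 alternatives, among them without control replicate 2, treated replicate 1 or treated replicate 3 (adjusted p = 0.040, 0.031 and 0.039). NRF2 targets pass by library size alone (adjusted p = 0.0073), with either gene class held equal, with no filter and by fry. Glycolysis passes once the gene length trend is removed (adjusted p = 0.023) and by fry, immediate early mRNAs with either class held equal and by fry, and cholesterol synthesis with ribosomal protein genes held equal and by fry. Among p53 targets 17 of 37 rose and 16 fell; Cdkn1a, for the cell cycle inhibitor p21, rose by 1.96 ± 0.17 but turns negative with either gene class held equal, and Mdm2, the p53 ubiquitin ligase gene, changed by −0.98 ± 0.17, a call lost with the length trend removed and a replicate block. Btg2, an antiproliferative gene, rose from 2.41 ± 0.45 to 63.4 ± 15.4 CPM. Of 54 immediate early and short-lived mRNAs 22 rose and 18 fell, with Snai1, a repressor gene, at −3.23 ± 0.31 beside the rises of Fos and Egr2. Heat shock genes had 9 of 23 higher and 9 lower. Hspa8, the constitutive HSP70 gene, fell from 1410 ± 144 to 69.1 ± 14.4 CPM, and Cryab, a small heat shock protein gene, rose from 2.22 ± 0.43 to 30.1 ± 5.9 CPM. Of 42 endoplasmic reticulum stress genes 16 rose and 15 fell, among them Nupr1 at 2.56 ± 0.17, not called with either class held equal, and Xbp1 at −3.16 ± 0.21. Glycolysis and glucose uptake genes had 11 of 20 higher and 4 lower, with the glucose transporter gene Slc2a1 at −4.79 ± 0.30 and hexokinase 2 (Hk2) at −3.50 ± 0.24. Pkm, for pyruvate kinase, rose by 1.87 ± 0.20 and turns negative with either class held equal. Of 22 cholesterol synthesis genes 8 fell and 4 rose, and Sqle, for squalene epoxidase, fell from 170 ± 10 to 4.99 ± 1.84 CPM. NRF2 targets had 16 of 27 higher and 10 lower; Gpx4, for a glutathione peroxidase that reduces lipid hydroperoxides, rose by 2.93 ± 0.27, and Gclc, for glutathione synthesis, changed by −3.19 ± 0.32. RNA polymerase II and elongation genes had 14 of 32 higher and 12 lower, with Polr2b at −3.34 ± 0.19 and Hexim1 at 2.08 ± 0.21, the latter negative with either class held equal. Of 19 snoRNA host genes 11 rose and 4 fell, with Snhg8 at 2.97 ± 0.19 and Gas5 at −2.41 ± 0.24. Counts adjusted over the list alone differed from those over all genes by 1 member in each direction for the BCL-2 list, and by 1 member for the mitochondrial, oxidative phosphorylation, G2/M and ribosome biogenesis lists.

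Markers of other cell types were mostly near 0. Of 18 macrophage genes 4 were tested, and Cd68 and Lyz2 rose by 3.79 ± 0.24 and 3.72 ± 0.28 to 25.7 ± 4.4 and 24.1 ± 7.0 CPM, with Cd14 at 1.61 ± 0.26 and Csf1r at 0.48 ± 0.62 (adjusted p = 0.496). Ptprc had 1 count and Itgam, C1qa and Laptm5 had 0 over the 6 libraries, while Tyrobp had 1, 0 and 1 counts in controls and 6, 3 and 3 after treatment, and Aif1 had 1, 1 and 2 and then 7, 3 and 4. The single tested lymphocyte marker, Lck, changed by −1.72 ± 0.50. The tested epithelial markers Krt14 and Muc1 rose by 1.63 ± 0.26 and 2.88 ± 0.47, and the tested endothelial markers Eng and Plvap by 0.46 ± 0.19 and 0.89 ± 0.27. Rises of Cd14, Krt14, Eng and Plvap are smaller than the 2.39 by which holding ribosomal protein genes equal lowers all genes.

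Fold change also followed gene length and gene class. In the shortest of 10 equal bins of tested genes, up to 1118 bases, 885 genes rose and 145 fell, with a median log2 change of 1.78. In the longest bin, from 9338 bases, 139 rose and 901 fell, with a median of −1.27. Across genes, Spearman's rho between log2 fold change and length was −0.42, where genes are not independent replicates. Among 16 gene biotypes tested, processed pseudogenes, which are copies of mRNAs, had 497 of 756 members higher and 87 lower (median 1.83 above all genes, camera adjusted p = 3.0e-10). Protein-coding genes lay 0.17 below (camera adjusted p = 2.4e-05), and transcribed processed pseudogenes and processed transcripts lay 1.28 and 0.74 above (camera adjusted p = 0.0022 and 0.044). With an estimated correlation none of these 4 calls held (lowest adjusted p = 0.065, for processed pseudogenes), and the processed transcript call was lost on leaving out control replicate 1 or any treated library.

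**Figure D4:**
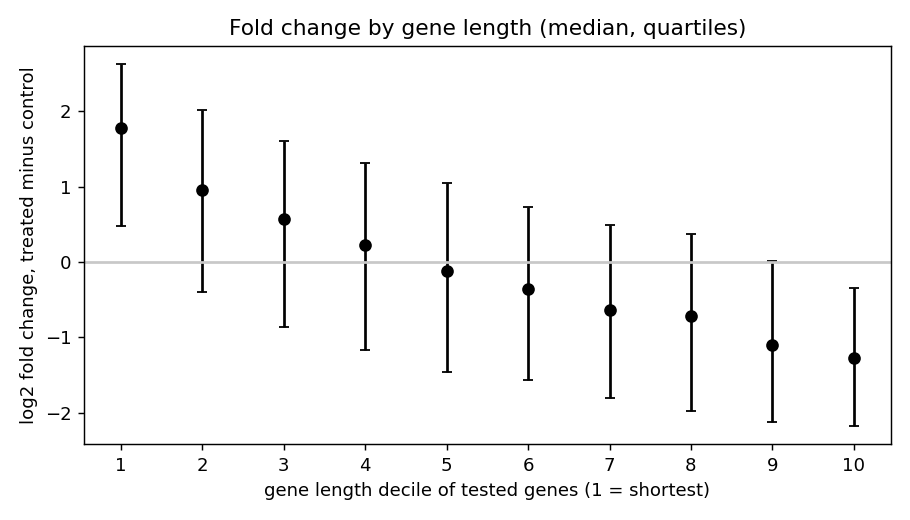
Median log2 fold change (dots) with quartiles (bars) of tested genes in 10 bins of gene length, from shortest to longest. The median goes from 1.78 in the shortest bin to −1.27 in the longest; with ribosomal protein or mitochondrially encoded genes held equal, all medians move down by over 2.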

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

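The GC content offset, the length and GC offsets for gene lists, and the estimated correlation for biotypes were chosen after the data were seen; the other alternatives were fixed before. Counts of changed genes stayed within 1.5 times of 4604 higher and 5337 lower, and of 3601 and 4395 at least 2-fold, in 76 of 88 comparisons. Leaving out 1 library gave 4125 to 4564 genes higher and 4928 to 5737 lower. Of the other 12, 11 came from scaling. By library size alone 2276 genes were higher, and 1476 higher and 6965 lower at least 2-fold. With ribosomal protein genes held equal 244 were higher and 10955 lower, 104 and 10261 at least 2-fold; with mitochondrially encoded genes held equal 345 and 10281, and 218 and 9792. These scalings lower all log2 changes by close to 1 constant, which is the cause. For mitochondrially encoded genes that constant rests largely on the mitochondrial rRNAs. On log2(FPKM + 1), 2683 genes were at least 2-fold lower, against 3302 of the same 10651 genes on log2(FPKM + 0.1), where only the added constant differs.

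Among values of named genes under an alternative, 2212 kept direction and side of the threshold, 60 kept direction but missed it, 9 newly passed (all of Casp8 or Tnfaip3) and 49 changed sign. With ribosomal protein genes held equal the log2 change turned for Gadd45b (−0.34), Ripk3 (−0.87), Rbck1 (−1.10), Cycs (−0.074), Casp1 (−0.23), Aldoc (−0.0034), Pkm (−0.53), Tyms (−1.48), Cenpa (−0.63), Ccnb2 (−0.84), Phgdh (−0.67), Hspe1 (−1.02), Tm7sf2 (−0.62), Ebp (−0.75), Polr2l (−0.30), Hexim1 (−0.25), Zfp580 (−0.23), Psmb3 (−0.19), Psma7 (−0.29), Nhp2 (−0.82), Mrto4 (−1.55), Cdkn1a (−0.43) and Tnf (−1.28). With mitochondrially encoded genes held equal it turned for Gadd45b (−0.044), Ripk3 (−0.62), Rbck1 (−0.86), Pkm (−0.29), Tyms (−1.19), Cenpa (−0.32), Ccnb2 (−0.55), Phgdh (−0.41), Hspe1 (−0.72), Tm7sf2 (−0.35), Ebp (−0.49), Hexim1 (−0.10), Nhp2 (−0.53), Mrto4 (−1.25), Cdkn1a (−0.20) and Tnf (−1.06). By library size alone it turned for Tyms (−0.11) and Mrto4 (−0.17). After the gene length offset it turned for Npc1 (0.33), Psmc2 (0.086), Psmd11 (0.35) and Tnfaip3 (0.83), and with the length offset and the replicate block for Npc1 (0.30), Psmc2 (0.049), Psmd11 (0.33) and Tnfaip3 (0.84); the cause was not tested.

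Of 450 list values, 404 kept direction and side. With an estimated correlation 0 lists were called higher and 0 lower, against 9 and 5 by camera's preset; unadjusted p-values under that setting were lowest for histones (0.0079) and G2/M genes (0.013), and DESeq2, voom and FPKM fits were not run on lists. By fry, which does not compare a list with other genes, 13 were higher and 8 lower. The proteasome median stayed 1.38 above all genes with ribosomal protein genes held equal while its test turned, the mitochondrially encoded list went to −0.47 after the length offset, and fry turned the heat shock list, whose median is 0.47 above all genes. Of the biotypes, 3 were called higher and 1 lower; 7 were higher by library size, 8 with ribosomal protein genes held equal, 8 with mitochondrially encoded genes held equal and 5 with the stricter filter, and with no filter 1 was higher and 0 lower. With an estimated correlation 0 biotypes were called higher and 0 lower. The cause was not tested.

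Shares of summed FPKM, which weight short genes more, gave these treated minus control differences in percentage points: 1.81 for mitochondrially encoded genes, 2.47 for mitochondrial rRNA, −1.34 for mitochondrial mRNA, 10.2 for ribosomal protein genes, 0.013 for histones, −0.091 for antisense genes, −0.11 for lincRNA, 4.42 for miRNA genes, 2.57 for processed pseudogenes, 0.80 for transcribed ones, 0.023 for processed transcripts, −10.5 for protein-coding genes and 13.5 for the 20 most abundant genes. The rRNA biotype turned from 0.037 to −0.013.

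Control and treated libraries share replicate numbers, which are not stated to pair the cultures. Deviations from the group means correlated at 0.22, −0.14 and 0.029 for numbers 1, 2 and 3. Not every library correlated best with its own number. These values show no consistent effect shared by number, but cannot exclude that cultures were handled in pairs. With a replicate block 4450 genes were higher and 5411 lower, 3490 and 4462 at least 2-fold. Genes with few counts, such as Cxcl2 in controls (3 counts) and Zfp748 after treatment (3 counts), are limited by depth.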

Other observations

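The tests of length bias on all called genes and on processed pseudogenes, of mitochondrial RNA and of other splits, and the transcription factor families, were chosen after the results were seen. Transcription factor genes, grouped by the family names of the deposited table, were lower as a class: of 856 tested, 542 fell and 93 rose, with a median log2 change 1.09 below that of all genes (camera adjusted p = 1.2e-06; adjusted p = 0.448 with an estimated correlation), and 246 of them also stand in the zinc finger list. In the ZBTB family 31 of 41 fell and 0 rose, and among the 22 MYB-type genes 18 fell and 1 rose. Of 8 SMAD-type genes 7 fell and 0 rose. Smad4, the shared partner of TGF-β and BMP signalling, went from 52.5 ± 1.8 to 3.51 ± 1.56 CPM, and Smad3 changed by −3.66 ± 0.32. Ctcf, for the insulator-binding protein, changed by −4.003 ± 0.320, and Cdc5l, a splicing factor gene with MYB repeats, by −4.15 ± 0.20. Max, the dimer partner of MYC, changed by −3.20 ± 0.21 and the circadian gene Arntl by −3.98 ± 0.23. Cold-shock domain genes had 5 of 7 higher and 0 lower, a call at the preset correlation (camera adjusted p = 0.041) that was lost once the length trend was removed (adjusted p = 0.067), although the shift over all genes went from 1.28 to 1.74. For each of these 4 families the adjusted p was 0.448 with an estimated correlation.

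Fold change fell with gene length (Spearman's rho −0.42 across 13290 genes). After the trend was removed, 7897 of 9941 called genes (79.4%) were called in the same direction. That argues against a bias following the deposited gene length alone as the whole cause of the called changes. A bias that adds to real changes stays open. The offset removes only the average trend with that length, so calls far off the trend were bound to remain. The test therefore cannot exclude a bias that acts otherwise, such as through the length of the expressed transcript. GC content as the whole cause of the trend is argued against too, with rho at −0.40 (95% bootstrap interval −0.41 to −0.38) after the GC trend was removed. Faster loss of mRNAs with ATTTA motifs is left open. The partial rho with motifs per kb of 3′ UTR was −0.029 (−0.051 to −0.011) in 11058 of 11470 protein-coding genes. It was taken given gene length, GC content, 3′ UTR length and 3′ UTR A+T content, so it cannot speak to the length trend itself. Unadjusted, rho was −0.18. The partial value is not the −0.1 or below predicted and lies on the side of the bound (−0.05) that counts against the explanation. Its interval just reaches that bound, and the demand that it clear the bound was made after the value was seen. Loss of long mRNAs in dying cells and RNA fragmentation were not tested, since coverage along transcripts was not analysed here.

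Mitochondrial rRNAs rose by a mean log2 change of 6.13 while the 12 tested mitochondrial mRNAs averaged 0.34 ± 0.91 (SD across genes). The mRNAs lay below the rRNAs by 5.79 (a difference of −5.79), so rRNAs and mRNAs did not rise equally. That gap is the pattern itself, so it is no separate test of more mitochondrial RNA as a whole. Carry-over of RNA without poly(A) tails may be a source, and cannot be told apart from a change in the cells: histone genes lay 3.24 above all genes, most at few control counts, but 24 snoRNA genes had a median of −1.28 relative to them. Favoured transcripts near the heavy-strand promoter stay open as a hypothesis, with rho between change and position at −0.42 across 11 heavy-strand mRNAs (permutation p = 0.203). The low-count mRNAs named above are among these, which makes that rho uncertain.

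Processed pseudogenes rose by a median of 1.83 above all genes. Reads shared with parent genes are a candidate explanation: for 164 pseudogenes whose symbol names a tested parent, 101 of them from ribosomal protein genes, the change followed that of the parent with Pearson's r at 0.85 (95% bootstrap interval 0.74 to 0.93; r at 0.91 without ribosomal protein parents), across genes that are not independent. A length bias between libraries as the whole cause cannot be told apart from other causes: with a length trend fitted on protein-coding genes removed, the median went from 2.00 above to 0.59 below that of protein-coding genes, or −29.7% of the shift (−34.6% to −22.3%), where a whole cause should leave close to 0. The lower of the bounds for that test was set after the value was seen. With a trend fitted on all genes removed, the shift over all genes was 0.14 and the call was lost (camera adjusted p = 0.66). That fit decides nothing here, since processed pseudogenes are 621 of the 1331 shortest genes and shape the trend. No biological explanation was tested.

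The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes past adjusted p 0.05, 1 of the 10 splits (the real one) gave as many as 9941, and the highest other gave 0; for those at least 2-fold, again 1 of 10, with 7996 against 0. For gene lists called by camera, 1 of 10 gave as many as 14, but the highest other gave 13, and for biotypes 7 of 10 gave as many as 4, with 10 the highest other. Each other split sets 2 libraries of 1 group and 1 of the other against the reverse, so it keeps part of the treatment difference.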
